A study of Mus musculus with 12 samples.

How the data were processed

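RNA from ventricle tissue of male C57BL/6J mice was sequenced in 12 samples, per the labels. The samples form 4 groups of 3, namely Sham, MI without a compound, and MI with either Fer-1 (Fer-1+MI) or Lip-1 (Lip-1+MI). MI stands for myocardial infarction by ligation of the left anterior descending coronary artery. Fer-1 is ferrostatin-1, given at 1 mg per kg per day, and Lip-1 is liproxstatin-1, given at 3 mg per kg per day. Both were started 24 h ahead of the ligation, per the labels' protocols. The time between ligation and tissue collection is not given in the sources used here. The labels do not say outright that the 3 replicates of a group are 3 animals, so all p-values measure the spread between these samples.

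Per the labels' protocols, RNA with an integrity number over 7 went into stranded poly(A) libraries, sequenced as paired reads of 150 bp on an Illumina NovaSeq. The authors deposited a table of counts per gene and a table of FPKM (fragments scaled by gene length and depth) per gene. Per the labels, the authors' processing names cutadapt 1.9, FastQC, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without the order of the steps. The deposited counts are whole numbers that were not normalised, and genes at 0 in every sample are listed. The deposited FPKM values were scaled by the authors for gene length and sequencing depth. Whether counting used the strand is not given in the sources used here.

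All 32623 genes of the count table and all 23660 genes of the FPKM table carry Ensembl identifiers with the ENSRNOG prefix, which Ensembl uses for rat, although the labels give mouse. The genome build is not given in the sources used here. Gene symbols and coordinates were taken from the FPKM table, which pairs them with the identifiers, and no mouse annotation was used. The reads may be mouse reads placed on a rat reference or rat reads under a mouse label, and the tables do not say which. Comparisons between groups share this limit, and levels of different genes within a sample should be read with it in mind. Where gene models overlap in the files' coordinates, as Gpx4 with Sbno2 and Fth1 with Best1, reads of the overlap could fall to either gene. The files hold several near-identical loci for ferritin light chain (Ftl1) and for ferroportin (Slc40a1), so both genes are uncertain.

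Total counts ranged from 45.5 to 60.8 M counts per sample (M for mega). A floor of 3 counts equals 0.0660 CPM (counts scaled to the same library size) in the smallest library. Such floors cover counting error only. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16910 of 32623 genes. In 10070 genes every sample was at 0. Counts were scaled with the trimmed mean of M values (TMM) and tested in edgeR 4.0.16 with robust quasi-likelihood F tests under R 4.3.3. All 12 samples entered 1 fit, with group as the only term and 8 residual degrees of freedom. The median prior degrees of freedom were 9.73 and the common biological coefficient of variation was 9.99%. All 6 contrasts and a test over all 4 groups were made, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Values in CPM use the TMM-scaled library sizes and are given as mean ± SD (n = 3), and log2 fold changes as estimate ± SE.

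Before the data were examined, 31 gene lists were fixed, with 693 entries of which 31 were not found in the files and are not analysed here. They cover ferroptosis, iron handling, antioxidant genes, cardiac stress, cardiomyocyte genes, ion channels, extracellular matrix, cytokines, fatty acid oxidation, respiratory chain and citric acid cycle, glycolysis, cell cycle, interferon response, cell death, hypoxia, immediate early genes, heat shock, endoplasmic reticulum (ER) stress and circadian genes. Marker lists cover fibroblasts, macrophages and monocytes, neutrophils, lymphocytes, endothelium, mural cells, erythroid cells, adipocytes, skeletal muscle, atrium, epicardium and lung. The 30 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists within a contrast. Camera with an estimated correlation and fry were alternatives. Counts of changed members are given over all genes tested and adjusted over the list alone. The named genes follow a rule fixed beforehand: per contrast the 8 largest rises and 8 largest falls with a group mean of at least 1 CPM and no overlap between the groups' samples, up to 3 members per list and direction with the smallest p, and 12 genes of ferroptosis and iron handling in every contrast.

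To ask whether ligation-changed genes moved back with a compound, the change with one compound was taken over the genes that differed between Sham and the group given the other compound. Those contrasts share no library. Contrasts of both compounds with MI share the MI libraries, so their similarity is set beside 20 simulations of unchanged groups. The test was checked on simulated counts for the contrast of Fer-1+MI with MI over 16604 genes. It called 39 of 65 genes changed by 0.5 on the log2 scale, 48 of 65 changed by 1, 54 of 66 changed by 2, and 4 unchanged genes.

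Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), only the 2 groups of a contrast, the replicate number as a block, other thresholds, and each library left out in turn. Pathway sets from the KEGG column of the FPKM table, Fisher's exact tests on them, a fit without mitochondrial genes and list counts with library size only were added after seeing the data. Of 324 pathways, 8 were picked then for camera, with adjustment over those 8 only. Those adjusted p-values do not count the search over all pathways. The KEGG ferroptosis set was adjusted together with the gene lists. Groups of 3 are too small for a test of single outlying samples. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Mitochondrial ferritin (Ftmt), named in the study's title, was not found in the files and is not analysed here.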

Results

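Per the labels, the samples are ventricle tissue. Gene expression was measured after a sham operation, after coronary ligation, and after ligation with pre-treatment by 1 of 2 inhibitors of ferroptosis. Ferroptosis is cell death driven by iron and by peroxidation of membrane lipids. Ferrostatin-1 (Fer-1) and liproxstatin-1 (Lip-1) are aromatic amines that trap lipid radicals. Each group (Sham, MI, Fer-1+MI, Lip-1+MI) had 3 samples. Total counts per sample, in M counts, were 45.5, 49.0 and 58.7 in Sham, 46.7, 60.7 and 48.3 in MI, 46.6, 58.9 and 60.2 in Fer-1+MI, and 60.1, 60.8 and 59.0 in Lip-1+MI. The identifiers in the files carry the prefix of rat genes while the labels give mouse, and the genome build is not given in the sources used here. Some heart muscle genes were high, with a mean over samples of 1234 FPKM for Myh6 and 5246 for Actc1. Others were low: Mb and Ckm were at 31.3 and 77.2 CPM in Fer-1+MI, and at 20.2 and 57.9 CPM in Lip-1+MI. Genes not particular to heart muscle were also high, with 4575 FPKM for Mgp, 2547 for Lcn2 and 1883 for Col1a1. Genes of blood and leukocytes were low: 8.98 for haemoglobin Hba-a1, 6.00 for Hbb, 3.65 for Ptprc and 1.75 for S100a8. Whether such levels suit whole infarcted ventricle was not tested, so readings of tissue and of leukocytes rest on the label. The largest difference lay between Sham and the 3 ligated groups. Across 16910 tested genes, 7491 differed among the 4 groups (edgeR, FDR under 0.05). The first principal component held 30.9% of the variance, with Sham samples from -61.5 to -52.2 and all ligated samples from 12.6 to 26.4. The second component held 8.97%.

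**Figure D1:**
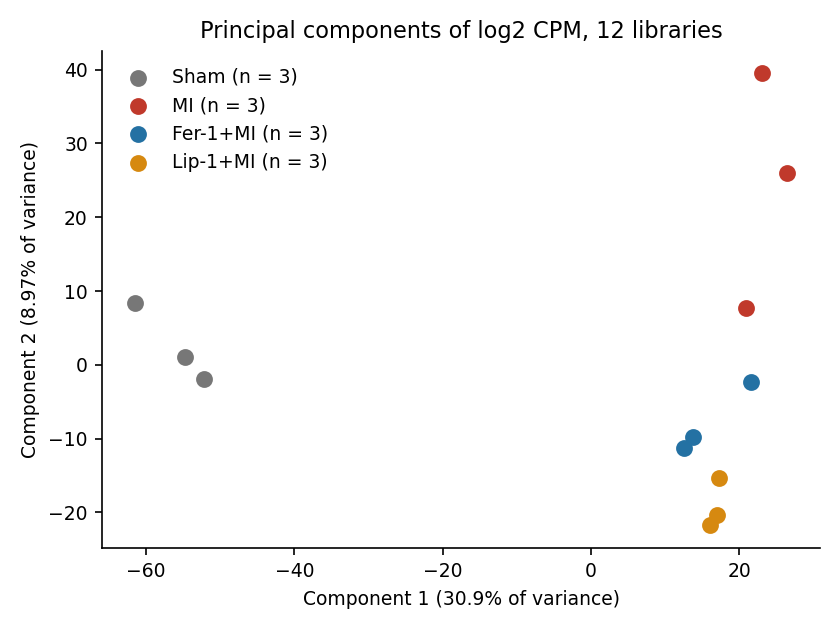
First against second principal component of log2 CPM for the 12 libraries, coloured by group, with the share of variance on each axis. Sham libraries lie at -61.5 to -52.2 on the first component and the 9 ligated libraries at 12.6 to 26.4.

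The comparison of MI with Sham asks what ligation does to the ventricle, and the design text singles out ferroptosis in it. Genes of inflammation, low oxygen and extracellular matrix rose in MI. Lists of glycolysis, cell cycle and cell death also rose, and their calls were lost (adjusted p = 0.0560, 0.194 and 0.224 with an estimated correlation). Lysosomal genes and genes of sterol synthesis fell, and heart muscle genes moved both ways. Gap junction genes split, with Gja1 up and Gja5 down. Within ferroptosis, genes moved both ways: Ptgs2, Slc7a11, Hmox1 and Acsl4 rose, and Gpx4 and Tfrc fell.

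In edgeR, 7369 genes differed between MI and Sham, of which 3860 were higher and 3509 lower in MI. Of these, 718 were higher and 290 lower by at least 2-fold. The split rests on the scaling: with library size only, 2414 were higher and 5943 lower, since the median over all genes then moved by -0.17. With FPKM values 2292 were higher and 5512 lower. No gene called under both scalings changed its sign.

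Cytokine genes had the highest median rise of the lists. Acod1 makes the metabolite itaconate in activated macrophages. It rose by 4.93 ± 0.26 on the log2 scale (adjusted p = 2.1e-07), from 1.74 ± 0.98 to 54.8 ± 1.9 CPM (ENSRNOG00000009919, chromosome 15, 93612971 to 93622358). Il1b, the cytokine interleukin-1 beta, rose by 4.69 ± 0.28 to 228 ± 8.1 CPM. Nos2, the inducible nitric oxide synthase, rose by 4.42 ± 0.40 to 653 ± 65 CPM. Sele, an endothelial adhesion molecule for leukocytes, rose by 4.65 ± 0.19. The growth factor genes Csf2 and Csf3 and the chemokine genes Ccl20 and Ccl22 also rose, by 4.02 to 4.90. Lif, a cytokine of the interleukin-6 family, rose by 3.72 ± 0.09, from 12.5 to 164 CPM. Of 29 cytokine genes, 23 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 2.3e-33, and 0.0197 with an estimated correlation). The protease gene Mmp9, high in neutrophils, rose by 2.51, the arginase gene Arg1 by 1.44, and the inflammasome gene Nlrp3 by 1.80.

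Genes induced by low oxygen rose as a block. All 16 hypoxia genes rose, over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.49 (camera adjusted p = 1.9e-42, and 0.00354 with an estimated correlation). Egln3, a prolyl hydroxylase that marks HIF for degradation, rose by 1.95 ± 0.05 from 174 ± 13 to 674 ± 26 CPM (adjusted p = 1.2e-14). Ndrg1 rose by 1.59 ± 0.05 and the collagen prolyl hydroxylase subunit P4ha1 by 1.01 ± 0.04. Of 22 glycolysis genes, 17 rose and 1 fell, and 18 rose and 2 fell adjusted over the list alone (camera adjusted p = 6.2e-16). That call was lost by a narrow margin (adjusted p = 0.0560 with an estimated correlation). The lactate exporter Slc16a3 rose by 1.36 ± 0.07, the glycolytic kinase Pgk1 by 0.85 and lactate dehydrogenase Ldha by 0.73.

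Of 40 matrix genes, 33 rose and 1 fell, and 35 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.1e-21, and 0.0257 with an estimated correlation). Thbs1, the matrix protein thrombospondin-1, rose by 1.48 ± 0.05 from 1100 ± 14 CPM (adjusted p = 6.8e-14). Lox, which crosslinks collagen, rose by 1.20 ± 0.04 and the contractile gene Tagln by 1.52 ± 0.06. The gelatinase Mmp2 was the matrix gene that fell, by -0.64 ± 0.05. Of 12 fibroblast markers 7 rose and 3 fell, with the same numbers adjusted over the list alone. Pdgfra rose by 1.21 and Dcn fell by 0.58. The fibroblast call (camera adjusted p = 0.0399) was lost without Sham 1 (adjusted p = 0.0583) and without MI 3 (0.0589), and adjusted p = 0.441 with an estimated correlation. Of 12 mural markers 8 rose, with the same number adjusted over the list alone (camera adjusted p = 0.00187; adjusted p = 0.0579 with an estimated correlation). Of 7 epicardial markers 6 rose, Krt8 by 1.34 and Wt1 by 0.61, with the same number adjusted over the list alone (camera adjusted p = 0.00521; adjusted p = 0.0579 with an estimated correlation).

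Heart muscle genes moved both ways. Lrrc10, a heart-specific gene, fell by 2.39 ± 0.10, to 10.5 ± 1.2 CPM in MI (adjusted p = 3.1e-12). Myh6, the alpha myosin heavy chain, fell by 0.43 ± 0.06, the calcium pump regulator Pln by 0.52 and the calcium release channel Ryr2 by 0.33. Nppa, the atrial natriuretic peptide and a stress marker of the ventricle, rose by 0.46 ± 0.06, and Casq1 and Fhl1 rose by 1.31 and 0.54. Of 16 cardiac stress genes, 12 rose, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00161; adjusted p = 0.326 with an estimated correlation). Of 23 cardiomyocyte genes 7 rose and 4 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.892), and with library size only 3 rose and 7 fell. Gap junctions carry current between heart cells. Gja1, the connexin 43 of working myocardium, rose by 0.92 ± 0.04 from 286 ± 8.6 to 539 ± 20 CPM (adjusted p = 1.1e-11). Gja5, the connexin 40 of conduction fibres, atrium and arteries, fell by 1.63 ± 0.09 from 72.0 ± 8.9 to 23.3 ± 1.6 CPM (adjusted p = 6.6e-11). The potassium channel genes Kcnd3 and Kcnj8 rose by 0.71 and 0.84, and Abcc9, the partner subunit of Kcnj8, fell by 0.51. Of 38 ion channel and conduction genes, 12 rose and 11 fell, and 15 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.892). With library size only, 10 of them rose and 14 fell.

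The remaining lists split by function. Of 29 cell cycle genes 21 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.000109; adjusted p = 0.194 with an estimated correlation). The mitotic genes Prc1, Top2a and Cdk1 rose by 0.83, 0.69 and 0.67. Of 24 cell death genes 14 rose and 1 fell, and 15 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00842; adjusted p = 0.224 with an estimated correlation). The death receptor Fas rose by 1.84 and the pore-forming Gsdmd of pyroptosis by 0.72. Of 19 immediate early genes 10 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.326 with an estimated correlation). Ier3 rose by 2.17 and Junb by 1.33. Of 24 interferon genes 2 rose and 10 fell, and 2 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.179, and 0.0199 without Sham 1). Stat2, a transcription factor of the interferon response, fell by 0.64, and Gbp2 rose by 1.58. Of 11 neutrophil markers 5 rose, with the same number adjusted over the list alone (camera adjusted p = 0.0137, and 0.214 with an estimated correlation). The leukocyte genes S100a8 and S100a9 stayed low. S100a8 was at 1.83 ± 0.47 FPKM in Sham and 2.15 ± 1.0 in MI, and S100a9 at 0.0354 and 0.0635. Ptprc was at 3.13 ± 0.06 and 4.06 ± 0.31 FPKM.

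For the lists that follow, camera at its preset correlation did not call a shift in MI against Sham, and counts adjusted over the list alone were the same unless given. Of 24 macrophage and monocyte markers 9 rose and 3 fell, of 15 endothelial markers 5 rose and 3 fell, and of 7 erythroid genes 4 fell. With library size only, 6 macrophage and monocyte markers rose and 6 fell, and 4 endothelial markers rose and 8 fell. Of 8 adipocyte genes 1 rose and 3 fell, of 8 skeletal muscle genes 1 fell, and of 7 atrial genes 2 rose and 1 fell (2 and 3 with library size only). The 6 tested lymphocyte markers had a median of -0.38 (camera adjusted p = 0.594). Tested in limma, their mean was lower by -0.41 (adjusted p = 0.0284), and the mean of the macrophage and monocyte markers higher by 0.19 (95% interval 0.07 to 0.32, adjusted p = 0.0135). The 2 tested lung genes had a median of -0.89, with no list test. Of 30 fatty acid oxidation genes 8 rose and 9 fell, and 10 rose and 9 fell adjusted over the list alone. With library size only, 1 of them rose and 13 fell. Of 51 genes of the respiratory chain and citric acid cycle 17 rose, and 9 rose adjusted over the list alone, while with library size only 2 rose and 9 fell. Of 13 heat shock genes 8 rose, and 10 rose and 1 fell adjusted over the list alone. Of 20 ER stress genes 12 rose and 1 fell, and 12 rose and 2 fell adjusted over the list alone, while with library size only 3 rose and 2 fell. Of 16 circadian genes 5 rose and 2 fell. Signs differed within lists: endothelial median -0.13 with mean 0.06 and an upward test, fatty acid oxidation median 0.12 with mean -0.06 and a downward test, and skeletal muscle median 0.24 with a downward test.

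Ferroptosis genes moved both ways in MI. Of 43 genes on the fixed list, 15 rose and 10 fell, with the same numbers adjusted over the list alone. The median was 0.04 and camera called no shift (adjusted p = 0.205; adjusted p = 0.498 with an estimated correlation). With library size only, 12 rose and 16 fell. The design text had singled out ferroptosis from Sham against MI in these same samples, so the count on the list alone is not independent evidence. Of the 39 tested genes in the KEGG ferroptosis pathway, added after seeing the data, 14 rose and 11 fell. Fisher's exact test over 324 pathways put these 25 changed genes at rank 50 (adjusted p = 0.373). Of 117 genes of the lysosome pathway, also added after seeing the data, 13 rose and 62 fell (camera adjusted p = 0.0119 with an estimated correlation). Of 19 genes of steroid biosynthesis 3 rose and 12 fell (0.0282). Both p-values were adjusted over only 8 KEGG sets picked after the results were seen.

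Ptgs2, the cyclooxygenase-2 often read as a marker of ferroptosis and itself an inflammatory gene, rose by 3.75 ± 0.24 from 19.2 ± 6.7 to 259 ± 34 CPM (adjusted p = 2.5e-06). Slc7a11, the cystine importer that feeds glutathione synthesis, rose by 0.99 ± 0.11 from 6.85 ± 0.54 to 13.6 ± 1.4 CPM (ENSRNOG00000010210, chromosome 2, 139453774 to 139528162). Gclc, which makes the glutathione precursor, rose by 1.13 ± 0.05 from 93.5 ± 5.0 to 204 ± 8.0 CPM. Hmox1, the haem oxygenase that frees iron from haem, rose by 0.83 ± 0.05 from 520 ± 23 to 926 ± 62 CPM (ENSRNOG00000014117, chromosome 19, 14508616 to 14515456). Acsl4, which loads membranes with oxidisable fatty acids, rose by 0.40 ± 0.05 (ENSRNOG00000019180, chromosome X, 113596239 to 113659944). Gpx4, the peroxidase that clears lipid peroxides, fell by 0.68 ± 0.15 from 89.7 ± 8.3 to 55.8 ± 7.2 CPM (adjusted p = 0.00517, ENSRNOG00000013604, chromosome 7, 12516352 to 12519154). Its model overlaps Sbno2 in the files. Tfrc, the transferrin receptor for iron uptake, fell by 0.78 ± 0.06 from 105 ± 5.6 to 61.2 ± 5.2 CPM (ENSRNOG00000001766, chromosome 11, 71397383 to 71419223). The uncertain ferritin light chain gene Ftl1 fell by 0.30. Ferritin heavy chain Fth1 (adjusted p = 0.411, ENSRNOG00000022619, chromosome 1, 226030938 to 226033228), the ferritin receptor Ncoa4 (0.840), the uncertain iron exporter Slc40a1 (0.636) and the coenzyme Q reductase Aifm2 (0.202) did not pass. With library size only, Fth1 (0.000641), Ncoa4 (0.00539) and Aifm2 (0.00651) passed as lower.

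Of 32 iron handling genes 7 rose and 8 fell, with the same numbers adjusted over the list alone, a median of -0.05, a mean of 0.01 and a downward test (camera adjusted p = 0.892). With library size only, 5 of them rose and 15 fell. The iron importers Slc11a2 and Slc25a37 rose by 0.74 and 1.11. Of 38 antioxidant genes 16 rose and 7 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0430; adjusted p = 0.441 with an estimated correlation). That call was lost without Sham 1 (0.0883), MI 1 (0.0680) or Lip-1+MI 1 (0.0592), and with library size only 12 rose and 13 fell. Txnrd1, a reductase of thioredoxin, rose by 0.94, while the peroxidase Gpx3 and the transferase Mgst1 fell by 0.68 and 0.91.

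**Figure D2:**
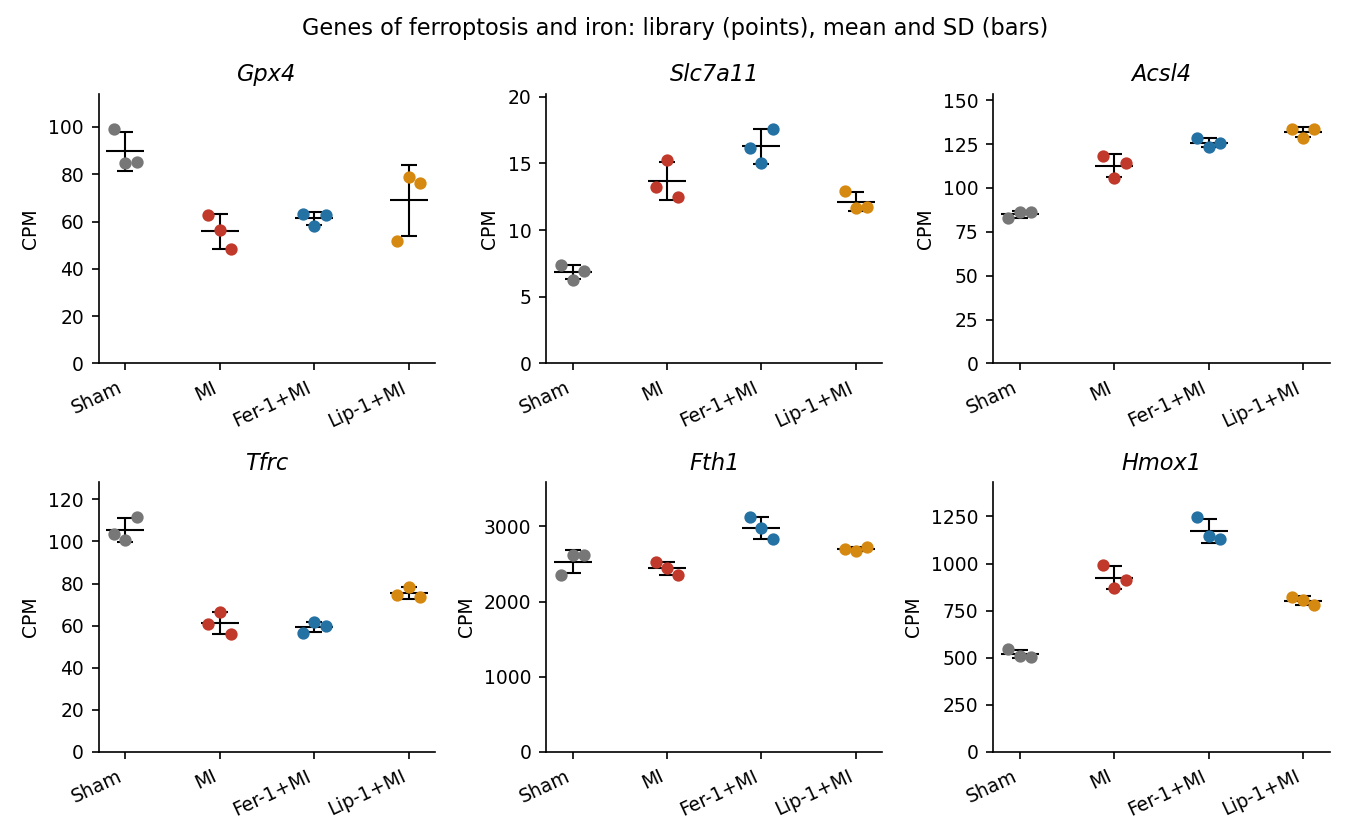
CPM per library of Gpx4, Slc7a11, Acsl4, Tfrc, Fth1 and Hmox1 in the 4 groups; points are libraries and bars mean and SD (n = 3). Gpx4 was lower in MI (55.8) than in Sham (89.7), and Hmox1 rose from 520 in Sham to 926 in MI and 1174 in Fer-1+MI.

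Fer-1+MI against MI asks what ferrostatin-1 changes in the ligated ventricle. Genes of matrix and cell division fell with Fer-1, as did the contractile genes Tagln and Smtn. Genes of iron handling rose, among them Hmox1 and Fth1. The inflammatory rise after ligation stayed: Il1b, Nos2 and Acod1 were not called between the groups. Gpx4, Slc7a11, Acsl4, Tfrc and Ptgs2 did not pass the threshold.

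In edgeR, 907 genes differed, 388 higher and 519 lower with Fer-1, of which 19 and 15 changed by at least 2-fold. Without 1 library the count fell to 569 (Fer-1+MI 3), 574 (Fer-1+MI 2) or 582 (MI 3). Tagln fell by 0.78 ± 0.06 from 1062 ± 50 to 617 ± 32 CPM (adjusted p = 3.7e-07), and Eln, the gene of elastin, fell by 0.77 ± 0.06 from 880 ± 93 to 517 ± 30 CPM (adjusted p = 1.2e-06). The collagen Col12a1 fell by 0.34, the smooth muscle gene Smtn by 0.59 and the growth factor binding protein Igfbp2 by 1.03 ± 0.10. Mmp2 rose by 0.46 ± 0.05 and Dcn by 0.51. Of 40 matrix genes 1 rose and 23 fell, and 3 rose and 31 fell adjusted over the list alone (camera adjusted p = 1.1e-25, and 0.0191 with an estimated correlation). Of 29 cell cycle genes 15 fell, and 22 fell adjusted over the list alone (camera adjusted p = 2.8e-19, and 0.0191 with an estimated correlation). Prc1 fell by 0.38 ± 0.05, Mki67 by 0.33 and Mcm5 by 0.43.

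Cell-type markers fell along with the matrix genes, so a shift in cell composition is not separated from a change within cells. Of 7 epicardial markers 2 fell, and 3 fell adjusted over the list alone (camera adjusted p = 0.00276; adjusted p = 0.0659 with an estimated correlation). Of 12 mural markers 1 fell, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.00658; adjusted p = 0.0956 with an estimated correlation). Of 12 fibroblast markers 1 rose and 4 fell, and 4 rose and 6 fell adjusted over the list alone. Camera did not call the fibroblast list (adjusted p = 0.0678), and called it without MI 1 (0.0261), MI 2 (0.0204) or Fer-1+MI 3 (0.0162). Tested in limma, the list means differed by -0.28 for epicardial (adjusted p = 0.00198), -0.34 for mural (0.0270) and -0.15 for fibroblast markers (0.0297). The mean of 8 skeletal muscle markers differed by -0.90 (limma, adjusted p = 0.00899) with a median of -0.64, but camera called no shift (adjusted p = 0.732) and the only marker called, Pvalb, rose, over the list alone as well. These markers were low, with means in MI from 0.221 to 4.18 CPM.

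Of 32 iron handling genes 7 rose, and 8 rose adjusted over the list alone (camera adjusted p = 5.0e-08, and 0.0286 with an estimated correlation). Cp, the ferroxidase ceruloplasmin, rose by 0.55 ± 0.06 from 178 ± 8.5 to 261 ± 18 CPM (adjusted p = 3.3e-05). Lcn2, which binds iron-carrying siderophores, rose by 0.71 ± 0.07 from 1963 ± 27 to 3210 ± 379 CPM. Hmox1 rose by 0.34 ± 0.05 from 926 ± 62 to 1174 ± 63 CPM (adjusted p = 0.000486), and Fth1 by 0.29 ± 0.05 (adjusted p = 0.00115). Of 43 ferroptosis genes 5 rose and 1 fell, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000182). That call was lost (adjusted p = 0.0733 with an estimated correlation). Of the 39 KEGG ferroptosis genes 6 rose, and that set kept its call (adjusted p = 0.0477 with an estimated correlation). Fisher's exact test on rising genes put it at rank 9 (adjusted p = 0.0472), and on genes changed either way at rank 43 (adjusted p = 0.426). Of 38 antioxidant genes 9 rose, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.4e-05; adjusted p = 0.0956 with an estimated correlation). Mgst1, Gsta4 and Gpx3, which use glutathione, rose by 0.62, 0.49 and 0.30. Changes that did not pass were 0.14 ± 0.16 for Gpx4 (adjusted p = 0.718), 0.25 ± 0.10 for Slc7a11 (0.181), -0.04 ± 0.06 for Tfrc (0.784), 0.15 ± 0.21 for Ptgs2 (0.794), 0.12 for Ncoa4 (0.194), 0.28 for Slc40a1 (0.182), 0.11 for Ftl1 (0.413) and 0.04 for Aifm2 (0.869). Acsl4 missed the threshold at 0.16 ± 0.05 (adjusted p = 0.0541) and passed it in DESeq2 (0.0173) and without MI 1 (0.0347).

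The largest rises with Fer-1 were Ces1d, a carboxylesterase, by 1.85 ± 0.27 to 2.81 CPM, the epithelial transcription factor Ehf from 0.680 to 1.93 CPM (adjusted p = 0.00722), and the calcium buffer Pvalb by 1.43 ± 0.18. The protease inhibitor Slpi rose by 1.16 ± 0.16 from 89.0 ± 2.0 to 199 ± 35 CPM, and the acute phase gene Orm1 by 1.17. Egr1, an immediate early transcription factor, rose by 0.71 ± 0.08. The embryonic myosin Myh3 fell most, by 1.69 ± 0.29 from 3.87 to 1.20 CPM. Nppa fell by 0.31 ± 0.06 (adjusted p = 0.00651). Of 16 cardiac stress genes 4 fell, and 8 fell adjusted over the list alone (camera adjusted p = 4.6e-08; adjusted p = 0.0956 with an estimated correlation). Of 20 ER stress genes 4 fell, and 7 fell adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.236 with an estimated correlation), with the serine synthesis gene Phgdh lower by -0.45.

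Lip-1+MI against MI asks the same of liproxstatin-1. Cyp1a1 and Aldh3a1, genes of foreign-compound metabolism, had the largest rises. Genes of cell division fell, and genes of lysosomes and sterol synthesis rose, the lysosome genes also with Fer-1. The matrix and fatty acid oxidation lists fell too, and both calls were lost (adjusted p = 0.0632 and 0.219 with an estimated correlation). Within ferroptosis, Tfrc, Acsl4 and Lpcat3 rose, and Gpx4, Slc7a11 and Ptgs2 did not pass.

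In edgeR, 1031 genes differed, 515 higher and 516 lower with Lip-1, of which 24 and 14 changed by at least 2-fold. Without 1 library the count fell to 661 (MI 3), 673 (Lip-1+MI 3) or 687 (Lip-1+MI 1). Cyp1a1, a cytochrome P450 that oxidises aromatic compounds, rose by 4.16 ± 0.32 from 0.724 ± 0.38 to 13.3 ± 2.9 CPM (adjusted p = 1.7e-06). Aldh3a1, an aldehyde dehydrogenase, rose by 3.53 ± 0.26 from 1.21 ± 0.41 to 13.9 ± 2.3 CPM (adjusted p = 5.2e-07). Ahrr, the repressor of the receptor, rose by 1.61 ± 0.15 from 4.68 ± 0.20 to 14.2 ± 2.2 CPM. Nqo1, a quinone reductase that also rose with Fer-1 (0.42, adjusted p = 0.000765), rose by 1.38 ± 0.07 from 33.6 ± 1.9 to 87.4 ± 5.1 CPM (adjusted p = 6.1e-10). Ces1d and Pvalb rose by 1.68 and 1.76, and Myh3 and Krt14 fell by 1.46 and 1.21.

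Of 29 cell cycle genes 21 fell, and 28 fell adjusted over the list alone (camera adjusted p = 4.7e-31, and 0.00452 with an estimated correlation). Mki67 fell by 0.46 ± 0.05 from 127 ± 5.1 to 92.6 ± 2.1 CPM and Mcm5 by 0.55 ± 0.07. Of 40 matrix genes 2 rose and 21 fell, and 2 rose and 23 fell adjusted over the list alone (camera adjusted p = 2.0e-17; adjusted p = 0.0632 with an estimated correlation). Eln fell by 0.67 ± 0.06 from 880 ± 93 to 553 ± 28 CPM (adjusted p = 4.0e-06), the main collagen gene Col1a1 by 0.41 ± 0.04 and Smtn by 0.72, while Mmp2 and Dcn rose by 0.53 and 0.68. Of 7 epicardial markers 2 fell, and 3 fell adjusted over the list alone (camera adjusted p = 0.0174, and 0.0535 without Lip-1+MI 3; adjusted p = 0.155 with an estimated correlation). Their mean differed by -0.24 in limma (adjusted p = 0.00694), and that of the fibroblast markers by -0.13 (adjusted p = 0.0934). Of 12 mural markers 3 fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.00282; adjusted p = 0.112 with an estimated correlation). The mean of the lymphocyte markers was lower by -0.47 in limma (adjusted p = 0.0417), and by -0.50 against Fer-1+MI (adjusted p = 0.0497), while camera called neither (adjusted p = 0.481 and 0.502). Their median against Fer-1+MI was 0.03, of the other sign. A shift in cell composition is not separated from a change within cells. Vwf, the endothelial clotting factor gene, fell by 0.71 ± 0.06 from 62.1 ± 3.7 to 38.0 ± 1.2 CPM (adjusted p = 1.0e-06). Gpnmb, a lysosomal membrane protein of macrophages and other cells, rose by 0.44 ± 0.05. Gja5 rose by 0.43 ± 0.09 to 31.4 ± 2.7 CPM (adjusted p = 0.00611), still under its Sham level of 72.0. Of 30 fatty acid oxidation genes 8 fell, and 11 fell adjusted over the list alone (camera adjusted p = 4.2e-07; adjusted p = 0.219 with an estimated correlation). Of 117 lysosome genes 41 rose, and of 19 steroid biosynthesis genes 12 rose (camera adjusted p = 0.000376 and 0.000210 with an estimated correlation). Both sets were added after seeing the data, and 13 lysosome genes rose with Fer-1 as well (adjusted p = 0.0176 with an estimated correlation). These adjustments covered only the 8 KEGG sets picked then. Pdk4, a kinase that blocks the oxidation of pyruvate, fell by 0.98 ± 0.14 (adjusted p = 0.000504), and the carnitine transferase Cpt1b by 0.48.

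Of 43 ferroptosis genes 10 rose and 4 fell, and 12 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.0426; adjusted p = 0.335 with an estimated correlation). The median was 0.08 and the mean -0.13, because Acsl6 was at 0 counts in all 3 Lip-1 libraries. The call was lost without MI 2 (0.0759), MI 3 (0.160), Fer-1+MI 1 (0.0537), Fer-1+MI 2 (0.0509) or Lip-1+MI 3 (0.0660). Of the 39 KEGG ferroptosis genes 11 rose and 3 fell (camera adjusted p = 0.00574; adjusted p = 0.198 with an estimated correlation). Fisher's exact test on rising genes put that set at rank 5 of 324 pathways (adjusted p = 6.3e-05). Tfrc rose by 0.30 ± 0.06 from 61.2 ± 5.2 to 75.5 ± 2.7 CPM (adjusted p = 0.00487), Acsl4 by 0.23 ± 0.05 (adjusted p = 0.00557) and the phospholipid acyltransferase Lpcat3 by 0.23. Hmox1 fell by 0.20 ± 0.05 (adjusted p = 0.0235), and that call was lost without MI 1 (0.126), MI 3 (0.0584), Lip-1+MI 2 (0.0660) or Lip-1+MI 3 (0.109). Gpx4 did not pass at 0.31 ± 0.15 (adjusted p = 0.329), and passed at 0.48 without Lip-1+MI 1 (0.00627). Slc7a11 (-0.17, adjusted p = 0.391), Fth1 (0.14, 0.0873), Ptgs2 (0.45, 0.306), Ncoa4 (0.11, 0.197), Slc40a1 (-0.29, 0.163), Ftl1 (0.07, 0.663) and Aifm2 (-0.16, 0.293) did not pass. Fth1 passed in DESeq2 (0.0297) and Ptgs2 without Sham 1 (0.0149). Of 32 iron handling genes 4 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00635; adjusted p = 0.219 with an estimated correlation), with Lcn2 up by 0.54.

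Lip-1+MI against Fer-1+MI tests directly where the compounds differ. Their structures differ: ferrostatin-1 is a small benzene ester with a cyclohexylamino group, and liproxstatin-1 is a larger spiro compound with a basic piperidine ring and a chlorobenzyl group. Their daily doses also differed, 1 against 3 mg per kg, so compound and dose changed together. Cyp1a1, Aldh3a1, Ahrr and Nqo1, which are among the targets of the aryl hydrocarbon receptor, and the sterol synthesis gene Msmo1 were higher with Lip-1. Hmox1, Gclc, Cat and 14 genes of fatty acid oxidation were higher with Fer-1. That list's call was lost (adjusted p = 0.0839 with an estimated correlation).

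In edgeR, 533 genes differed, 295 higher and 238 lower with Lip-1, of which 16 and 15 differed by at least 2-fold. With library size only, 234 were higher and 297 lower. Without 1 library the count fell to 304 (Lip-1+MI 2), 311 (Lip-1+MI 1) or 337 (Fer-1+MI 2). Cyp1a1 was higher with Lip-1 by 4.34 ± 0.33 (adjusted p = 1.5e-06), at 13.3 ± 2.9 against 0.663 ± 0.18 CPM. Aldh3a1 was higher by 3.25 ± 0.25, Ahrr by 2.02 ± 0.16 and Nqo1 by 0.96 ± 0.07, at 87.4 ± 5.1 against 44.9 ± 0.49 CPM. Msmo1, a methyl sterol oxidase of cholesterol synthesis, was higher by 1.33 ± 0.09, at 65.9 ± 3.1 against 26.3 ± 4.5 CPM (adjusted p = 7.6e-08). Grem1, an antagonist of bone morphogenetic proteins, was also higher, at 38.2 ± 5.2 against 17.2 ± 1.5 CPM (adjusted p = 1.8e-06).

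Of 30 fatty acid oxidation genes, 14 were lower with Lip-1, and 20 were lower adjusted over the list alone, with a median of -0.22 (camera adjusted p = 4.0e-23; adjusted p = 0.0839 with an estimated correlation). The mean over the list, tested in limma, differed by -0.31 (95% interval -0.44 to -0.18, adjusted p = 0.00575). Pdk4 was lower by -1.55 ± 0.14, at 8.55 ± 2.2 against 25.0 ± 2.1 CPM (adjusted p = 6.4e-06). The acyl-CoA synthetase Acsl1 and the dehydrogenase Acadvl were lower by -0.63 and -0.35. Hmox1 was lower by -0.55 ± 0.05, at 803 ± 23 against 1174 ± 63 CPM (adjusted p = 4.4e-06), Gclc by -0.37 ± 0.05 and catalase (Cat) by -0.37. Of 32 iron handling genes 1 was higher and 4 lower, and 3 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0205; adjusted p = 0.383 with an estimated correlation). Of 38 antioxidant genes 2 were higher and 5 lower, and 2 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.00814; adjusted p = 0.383 with an estimated correlation). By fry neither passed (adjusted p = 0.0807 and 0.0695). The iron call was also lost without Fer-1+MI 1 (0.0881), Lip-1+MI 1 (0.0558) or Lip-1+MI 2 (0.0989), and the antioxidant call without Lip-1+MI 1 (0.0558). Vwf was lower by -0.80 ± 0.06 and the receptor gene Kdr by -0.44. Of 15 endothelial markers 1 was higher and 4 lower, and 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.166 with an estimated correlation). The mean of the 8 low skeletal muscle markers was higher with Lip-1 (95% interval 0.68 to 1.62, limma adjusted p = 0.00575; camera adjusted p = 0.00814; adjusted p = 0.159 with an estimated correlation). Tfrc was higher with Lip-1 by 0.35 ± 0.06 (adjusted p = 0.00264), Acsl3 by 0.34 and Gja5 by 0.54 ± 0.09. The uncertain Slc40a1 was lower by -0.57. Slc7a11 was lower by -0.42 (adjusted p = 0.0257), which was lost without Fer-1+MI 1 (0.0501), Fer-1+MI 3 (0.123), Lip-1+MI 2 (0.109) or Lip-1+MI 3 (0.0944). Of 43 ferroptosis genes 2 were higher and 6 lower, and 5 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.112).

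No difference passed for Gpx4 (0.17, 95% interval -0.18 to 0.52), Acsl4 (0.07, -0.03 to 0.17), Ptgs2 (0.30, -0.18 to 0.78), Fth1 (-0.14, adjusted p = 0.142) and Ftl1 (-0.04, adjusted p = 0.849). The mean of the matrix list differed by 0.04 (-0.04 to 0.11), of the hypoxia list by -0.04 (-0.13 to 0.06) and of the cytokine list by -0.16 (-0.38 to 0.07). With all libraries camera called none of these 3 lists. It called the matrix list without Fer-1+MI 1 (0.0359), Fer-1+MI 3 (0.0387) or Lip-1+MI 3 (0.0401), and the cytokine list without Fer-1+MI 3 (0.0432) or Lip-1+MI 3 (0.0423). The medians of these lists between MI and Sham were 0.56, 1.49 and 1.66.

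**Figure D3:**
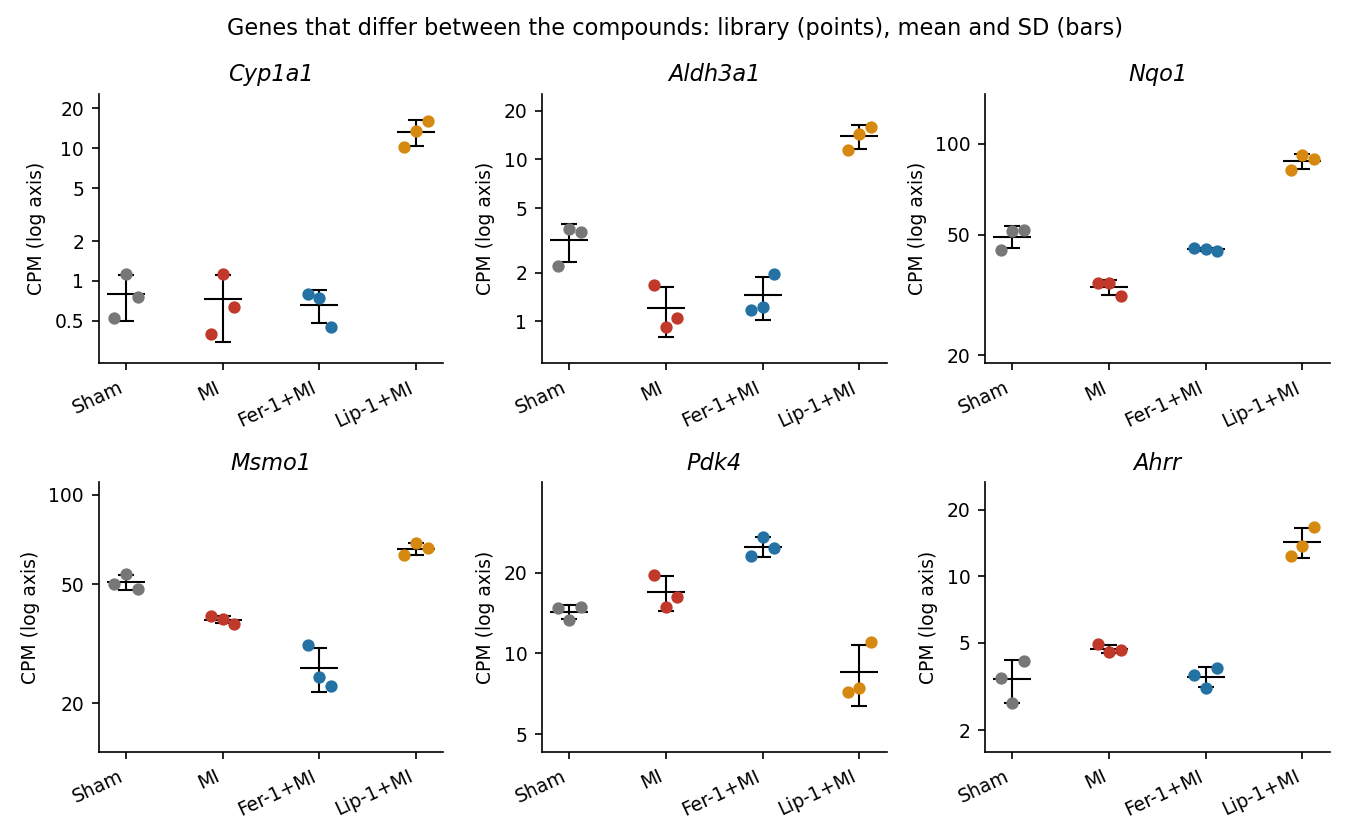
CPM per library on a log axis for Cyp1a1, Aldh3a1, Nqo1, Msmo1, Pdk4 and Ahrr in the 4 groups; points are libraries and bars mean and SD (n = 3). Cyp1a1 reached 13.3 CPM with Lip-1 and stayed at 0.663 with Fer-1, and Pdk4 was at 8.55 with Lip-1 and 25.0 with Fer-1.

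Both treated groups were also set against Sham, to ask how far they stayed from it and whether the genes changed by ligation moved back. Most of the ligation response remained with either compound: inflammatory and hypoxia genes stayed far from Sham. Many other genes changed by ligation lay slightly nearer to Sham. Lrrc10 recovered a small part of its fall with both compounds, and Hmox1 moved further from Sham with Fer-1. Gpx4 stayed lower than Sham with Fer-1, and its difference from Sham did not pass with Lip-1. In the direct contrast no difference in Gpx4 between the compounds passed (edgeR adjusted p = 0.708).

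Between Fer-1+MI and Sham 6137 genes differed in edgeR, 3306 higher and 2831 lower. Between Lip-1+MI and Sham 6556 differed, 3514 higher and 3042 lower. With library size only, the splits were 1980 against 5325 and 1994 against 5909. Acod1 remained higher by 5.01 with Fer-1 and 5.05 with Lip-1, Il1b by 4.51 and 4.56, Nos2 by 4.67 and 4.78, and Egln3 by 1.96 with each. Lrrc10 was lower than Sham by -1.78 ± 0.10 with Fer-1 and -1.87 ± 0.10 with Lip-1, against -2.39 in MI, and higher than in MI by 0.61 with Fer-1 (adjusted p = 0.00129) and 0.52 with Lip-1 (0.0043). Hmox1 was higher than Sham by 1.17 ± 0.05 with Fer-1 and 0.63 ± 0.05 with Lip-1. Tfrc was lower by -0.83 and -0.48. Gpx4 was lower by -0.55 with Fer-1 (adjusted p = 0.0196) and -0.38 with Lip-1 (adjusted p = 0.0802).

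Of the 6556 genes that differed between Lip-1+MI and Sham, 63.0% moved toward Sham between MI and Fer-1+MI, with a median step of 0.0493. Among all 6556 genes, 488 were called back and 118 further away. Of the 6137 genes that differed between Fer-1+MI and Sham, 59.4% moved toward Sham between MI and Lip-1+MI, with a median step of 0.0364, 523 called back and 143 further. In 20 simulations with unchanged compounds these shares averaged 49.8% and 49.9% and reached at most 50.7% and 51.0%. Each gene was drawn independently there, so the spread of the simulated shares is too narrow. Over the 7369 genes that differed between MI and Sham, the shares were 74.8% and 70.5%. Those share the MI libraries, and their simulated means were 57.3% and 57.3%.

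The 2 compounds' changes against MI shared direction for 70.5% of genes, with a correlation across genes of 0.502 and a covariance of 0.125. Both rest on the same MI libraries, and genes are not independent replicates. Simulated unchanged groups gave 66.9%, a correlation of 0.514 and a covariance of 0.0588. The covariance beyond the simulated one was 0.0660, while the correlation was not above the simulated one. Called in the same direction were 405 genes, 170 up and 235 down, against 11.8 and 15.8 for independent lists. The simulations gave at most 1 such gene. With no change simulated hardly any gene is called with either compound, so that overlap was bound to be small and is no yardstick. Only 11 genes were called in opposite directions. With 3 MI libraries each compound cannot be given MI libraries of its own, so part of the excess may come from the shared ones.

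**Figure D4:**
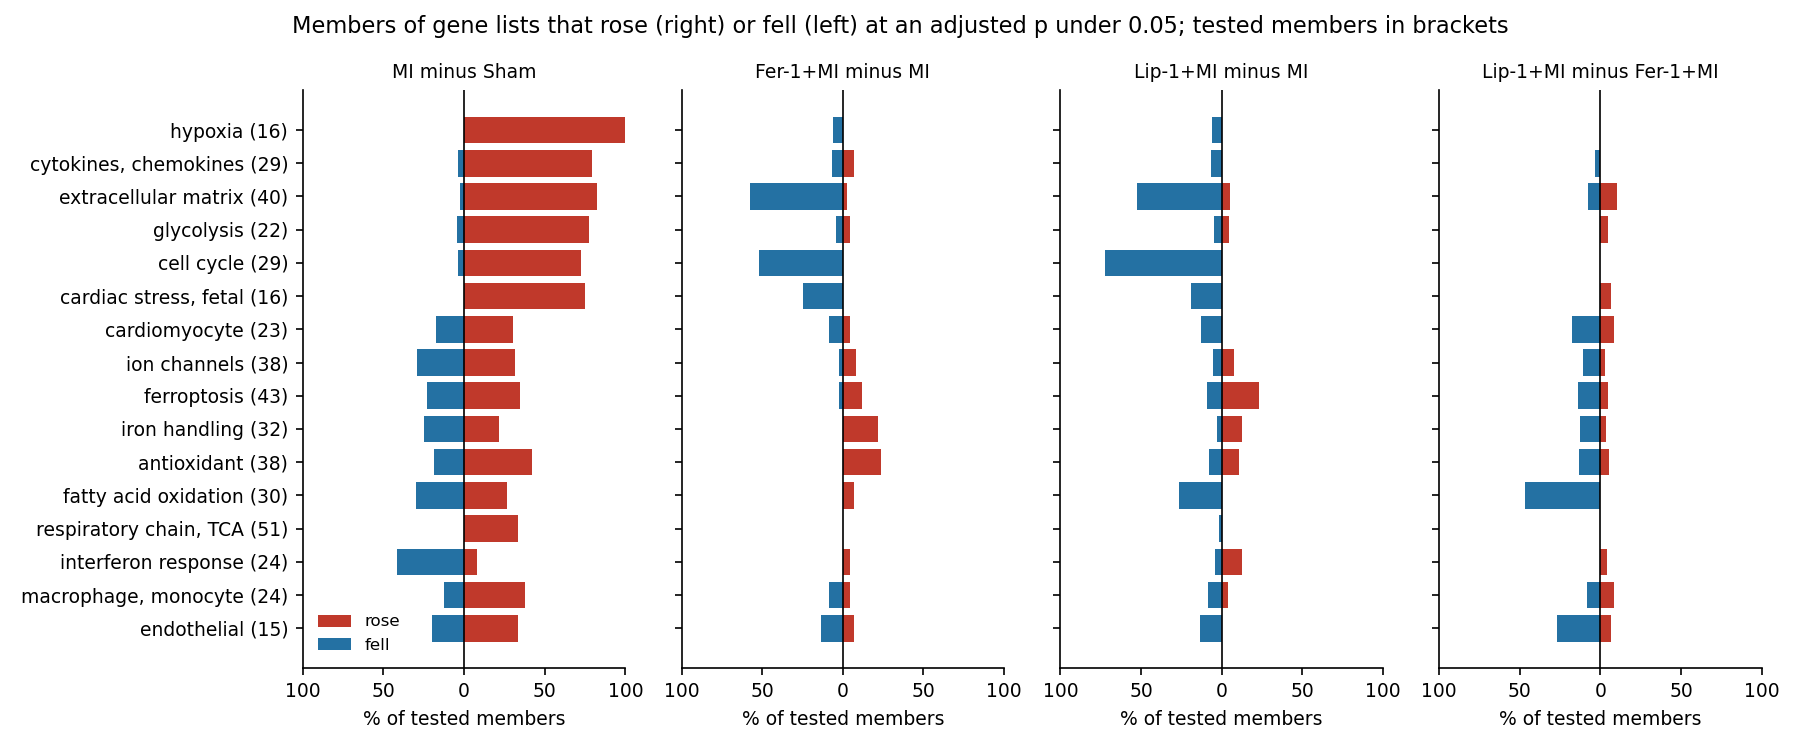
Share of tested members of 16 gene lists that rose or fell (edgeR, FDR under 0.05), in percent, in the contrasts MI against Sham, Fer-1+MI against MI, Lip-1+MI against MI and Lip-1+MI against Fer-1+MI. All 16 hypoxia genes rose in MI, and 15 and 21 of 29 cell cycle genes fell with Fer-1 and Lip-1. With library size only the majority direction in MI flips for the ferroptosis, antioxidant, cardiomyocyte, ion channel, endothelial and respiratory chain lists. It also flips with Fer-1 for macrophages and with Lip-1 for antioxidant genes.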

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

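The direct contrast and the splits of libraries were set beforehand, while the pattern of receptor targets, the pattern of return toward Sham and the prediction rules for the return were chosen only after the results were seen. The 2 compounds were expected to act alike as radical traps, yet 533 genes differed between Lip-1+MI and Fer-1+MI in the direct contrast. Cyp1a1 was higher with Lip-1 by 4.34, Pdk4 lower by -1.55, Hmox1 lower by -0.55, and the median of the fatty acid oxidation list was -0.22. Each of these is a difference between groups of 3 given different compounds at different doses, and the 2 cannot be separated here.

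Cyp1a1, Aldh3a1, Ahrr and Nqo1 were higher with Lip-1, and all 4 are targets of the aryl hydrocarbon receptor. Nqo1 is also on the antioxidant list, and it rose with Fer-1 against MI by 0.42 (adjusted p = 0.000765), so its rise is not particular to the receptor or to Lip-1. They drew attention to the receptor, so the other targets were taken as the test. Their median between Lip-1+MI and Fer-1+MI was 0.19, short of the bound of 0.2 set beforehand, so by the rule as written the set did not respond. The shortfall was less than the spread over genes (SD 0.414), and taking that spread into account was decided after the value was seen, so the response of the targets as a set stays open. Of these, Cyp1b1 was higher by 0.83 (adjusted p = 4.5e-06), while Tiparp (0.06, adjusted p = 0.745) and Ugt1a6 (0.19, adjusted p = 0.181) did not pass. Against MI the median of these 3 was 0.37 and each was called higher with Lip-1, Cyp1b1 by 0.95 (adjusted p = 1.2e-06), Tiparp by 0.23 (0.0331) and Ugt1a6 by 0.37 (0.00248). That contrast was not the one the rule named. RNA of liver or lung cells was tested by their marker genes: the summed CPM in Lip-1+MI over Fer-1+MI was 0.940. For larger Lip-1+MI libraries, all libraries were thinned to 45469259 counts, after which Cyp1a1 was still higher by 4.41. Thinning lowers all counts of a library in proportion and leaves the expected fold change in place. It therefore could not decide that explanation. The liver and lung markers do not account for the rise of Cyp1a1. Lip-1, its dose or a product of it may act on the receptor, which these values leave open.

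Genes changed by ligation lay nearer to Sham with both compounds. Shared MI libraries were the first explanation tested. Of genes called in Fer-1+MI against Sham, 59.4% moved toward Sham with Lip-1, while simulated unchanged groups reached at most 51.0%. The simulations drew each gene independently, while real genes vary together, so their narrow range cannot exclude chance values of the 3 MI libraries. By fry p was 0.00355 for Lip-1 and 0.00291 for Fer-1. Of 20 simulations 3 and 1 gave a fry p under 0.05, the lowest 0.000489 and 0.000508. A single MI library out of line was the second: the lowest share without 1 MI library was 57.5%. A difference of all 3 MI samples from the other ligated samples for a reason other than the compounds, such as a larger infarct, stays open and could give the same shares. The mitochondrial share of counts moved with the pattern: it was lowest in MI (5.38 ± 0.24%), against 6.78 ± 0.31% in Sham, 6.26 ± 0.42% in Fer-1+MI and 6.11 ± 0.20% in Lip-1+MI. A difference in tissue composition or library quality is therefore not excluded. Without mitochondrial-chromosome genes, 888 genes differed in Fer-1+MI against MI and 1032 in Lip-1+MI against MI, and the shares moving toward Sham were not computed in that fit.

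The organism of the RNA is left open: all 32623 genes carry rat identifiers and the labels give mouse.

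Libraries were also regrouped at random. For each of the 6 pairwise contrasts the real grouping was 1 of 10, too few for a share under 0.05. The real count and the highest other were 7369 and 1 for MI against Sham, 907 and 33 for Fer-1+MI against MI, 1031 and 0 for Lip-1+MI against MI, 533 and 0 for Lip-1+MI against Fer-1+MI, 6137 and 0 for Fer-1+MI against Sham, and 6556 and 0 for Lip-1+MI against Sham. Over all 4 groups the real count was 7491, the highest of 100 groupings with the real one included, and the highest other was 4312. That argues against chance only for a difference somewhere among the 4 groups. Sham lay far from all ligated samples, so a high count can come from that gap alone. The count over all groups therefore cannot decide whether the differences among the ligated groups arose by chance.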

How the results depend on the processing

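The alternatives were fixed before the data were seen, except the KEGG pathway sets, the fit without mitochondrial genes, the list counts with library size only and the check on abundant genes, which were chosen only after the results were seen. With a 2-fold limit 1008 genes differed in MI against Sham, 34 in Fer-1+MI against MI, 38 in Lip-1+MI against MI, 31 in Lip-1+MI against Fer-1+MI, 822 in Fer-1+MI against Sham and 838 in Lip-1+MI against Sham. For Fer-1+MI against MI the count was 1397 at FDR under 0.10, 550 with the 2 groups only and 552 with log2(FPKM + 1). Log2(FPKM + 1) gave 615 for Lip-1+MI against MI and 252 for Lip-1+MI against Fer-1+MI. Leaving out 1 library gave 569 (Fer-1+MI 3) to 1071 (Fer-1+MI 1), 661 (MI 3) to 1134 (Fer-1+MI 1) and 304 (Lip-1+MI 2) to 552 (MI 2) for these 3 contrasts.

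The ferroptosis list gave p = 7.5e-05 by fry in MI against Sham, where camera gave 0.205, 0.498 with an estimated correlation and 0.120 to 0.267 without 1 library. In Fer-1+MI against MI it gave 0.000182, 0.0733 with an estimated correlation and 1.4e-05 to 0.00241 without 1 library. In Lip-1+MI against MI it gave 0.0426, 0.335 with an estimated correlation, 0.0588 with the replicate block and 0.0132 (without MI 1) to 0.160 (without MI 3). The call with Lip-1 is therefore not firm. The immediate early list with Fer-1 ranged from 0.00106 (without Fer-1+MI 3) to 0.847 and reversed (without Fer-1+MI 1). Slc25a20 in MI against Sham turned to -0.0197 with library size only and -0.0117 with log2(FPKM + 1).

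The correlation of the compounds' changes across genes was 0.502, from 0.418 (without Fer-1+MI 1) to 0.668 (without MI 2). Genes called in the same direction were 405, from 257 (without MI 3) to 419 (without MI 2), and 615 at FDR under 0.10. Replicate numbers as a block gave 1152, 1272 and 676 genes for the contrasts among ligated groups, and of 18 same-numbered pairs the correlations ran from -0.0236 to 0.0879, none past the limit of 0.1 set for pairing. As a hint from the data only, 9 of 12 libraries correlated best with their own number, and the median was 0.0143 for same-numbered and -0.00886 for other-numbered pairs. A shared batch by number is neither shown nor excluded. Without the 200 most abundant genes the median between MI and Sham with library size only stayed at -0.14.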

Other observations

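The lysosome and steroid biosynthesis pattern was chosen only after the results were seen, and so were the lists of sterol targets and of proton pump subunits. Those 2 lists were written before their own values were read. Lysosome genes were higher with Lip-1 than with Fer-1 (camera adjusted p = 0.0108 with an estimated correlation). That p was adjusted over only 8 KEGG sets picked on the same data (unadjusted p = 0.00270), so it is not independent evidence. No MI library enters that contrast, so shared MI libraries do not account for the difference between the compounds. It cannot decide whether they account for the rise over MI. The median was 0.130 with Lip-1 and 0.0852 with Fer-1 against MI, and 0.0833 between the compounds. The median of 12 targets of SREBP2, the regulator of cholesterol synthesis, was 0.72 between Lip-1+MI and Fer-1+MI, with Hmgcs1 at 0.82, Idi1 at 1.08 and Fdps at 0.83. Part of this came from lower values with Fer-1. Against MI the median was 0.55 with Lip-1 and -0.10 with Fer-1, and Idi1 changed by 0.66 and -0.42. The median of 8 subunits of the lysosomal proton pump was 0.20 between Lip-1+MI and Fer-1+MI (camera p = 0.00231 with an estimated correlation), and 7 of them rose with Lip-1 against MI. More macrophages were tested by their markers: the upper limit of the shift of that list was 0.0697, below the lysosome median of 0.13 between Lip-1+MI and MI, and this rule was written after the values were seen. Between the compounds the same comparison fails, with an upper limit of 0.127 against a lysosome median of 0.08, so more macrophages with Lip-1 than with Fer-1 are not excluded. Lysosome genes also rose with Fer-1 against MI (13 of 117, adjusted p = 0.0176 with an estimated correlation), so their rise is not particular to Lip-1. A partial return of genes lowered by ligation may be part of the rise. Of 54 lysosome genes lower in Fer-1+MI than in Sham, 30 rose in Lip-1+MI against MI, in contrasts that share no library, against 41 of all 117, and no test was made of this overlap. Against Sham, 33 lysosome genes were still lower with Lip-1 and 19 higher, and of the steroid biosynthesis genes 4 were higher and 4 lower. Liproxstatin-1 is a basic amine, and such amines may accumulate in lysosomes and raise both gene groups. For lysosome genes that reading would have to explain the larger rise with Lip-1 only, and it does not explain their rise with Fer-1. Sterol genes did not rise with Fer-1 against MI. Of 19 steroid biosynthesis genes 1 rose and 2 fell, and of 12 SREBP2 targets 3 fell (camera adjusted p = 0.00188, and 0.127 with an estimated correlation). A milder response to ligation would lift genes that ligation lowered without any action on lysosomes. With Fer-1 lysosome genes rose and sterol genes did not, so a milder response alone does not cover both. The cause is left open. A block in an enzyme of sterol synthesis could raise the sterol genes as well. Staining of lysosomes and measurement of sterol intermediates in treated hearts would separate these readings.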
